A study of Homo sapiens with 27 samples.

How the data were processed

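RNA sequencing was deposited for 27 libraries in 9 groups of 3: cell cultures of MCF10A, MCF10A-D4, MCFDCIS and MCFDCIS-D4, and xenograft tumours of MCFDCIS at W2 and W5, of MCFDCIS-D4 at W5, and of a mixture of MCFDCIS and MCFDCIS-D4 cells (Mix) at W2 and W5. W2 and W5 were read as weeks 2 and 5. Per the labels, libraries were prepared from total RNA with ribosomal RNA removed. Groups were taken from the sample titles. The series text records that the titles of the MCF10A and MCF10A-D4 samples were exchanged in a later update, and the column names of these samples match the current titles. The library names of MCF10A-D4 and the column and library names of MCFDCIS-D4 cells do not name D4, so the latter were matched to their titles through the library names in the descriptions. Those of MCFDCIS-D4 cells read D10, while those of MCFDCIS-D4 tumours read D4. The names therefore do not show that the cultured line is the one grown as tumours. The labels do not say how the D4 lines were made. Each background had a single D4 line in culture, so D4 cannot be separated from other differences between that line and its parent. A D4 effect below means the difference between a D4 line and its parent. The design text speaks of pooled xenografts, and it does not say whether a replicate is 1 tumour or a pool. Nothing states that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

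The deposited values are a signal per gene, in reads divided by the library total (CPM) with a further scaling factor for each library, and come as 1 table for cells and 1 for xenografts. The submitters' processing notes name STAR, edgeR and the genome build hg19. Aligner settings, the counting tool, the annotation and versions are not given in the sources used here. There are 13937 genes for cells and 16159 for xenografts, of which 460 and 752 have no symbol. Column sums ran from 916911 to 1095590. In every library 100% of the values were whole multiples of the value of 1 read, within a tolerance of 0.01 reads, so reads per gene could be recovered: 25022960 to 37011458 reads in the cell libraries and 18839251 to 30166771 in the xenograft libraries. A single read was worth 0.0262 CPM in the deepest scaling and 0.0521 CPM in the shallowest, so a gene under 1 CPM rests on few reads and carries a larger counting error. Reads from mouse host cells that align to human genes would be counted as human, and the tables hold no means of separating them.

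Values were tested as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, separately in each table because the tables were scaled separately. Genes with at least 1 CPM in at least 3 libraries were kept, which left 13597 genes in cells and 15677 in xenografts. All groups of a table shared 1 estimate of the spread, with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called when its adjusted p was under 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates changes of genes with few reads. There were 9 comparisons of groups and 2 interactions, which test whether an effect differs between lines or between tumour compositions. Permutation tests of 3 libraries against 3 went through all splits, were two-sided and cannot give a p below 0.1.

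Gene groups were 35 lists, and these, the tests and the rule for named genes were fixed before the data were examined. They cover mammary lineage, differentiation, proliferation, metabolism, stress, signalling and matrix genes, together with fibroblast, adipocyte, macrophage and myeloid, endothelial, skeletal muscle, lymphocyte and erythroid markers for other cells that a mammary fat pad tumour could hold. Lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. The estimate used all groups of a table, so it also holds the spread of groups not compared. It was not made again with libraries left out. Of 370 tests of a list in a comparison, 164 passed with the preset value and 5 with the estimated value. Counts of members adjusted over the list alone are given beside those adjusted over all genes. The lymphocyte list had 2 genes in the xenograft table and 1 in the cell table, too few to test, and the erythroid list had 3 genes in the xenograft table.

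The rule for genes named in the text takes NCOA3, the 8 largest rises and 8 largest falls in the main comparisons (5 and 5 in the others, 4 and 4 in interactions), and up to 4 called members of each list. Of the genes it takes, 1 is not reported here. The largest changes were taken among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups. Genes without symbols, clone names, pseudogenes, antisense names and small RNAs were counted but not named. Near-identical copies can share reads, so CYP4Z1 (with CYP4Z2P), SPRR2A, the MT1 genes, histones and mitochondrially encoded genes with nuclear copies are uncertain. The strand setting of the counting is not given, so overlapping genes cannot be separated. Coordinates are from the GRCh37 annotation in the reference, the assembly behind hg19, and none are given for mitochondrial genes.

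The alternatives were pseudocounts of 0.1 and 1 CPM, no filter, a mean of at least 5 CPM, rescaling to a median log ratio of 0, no intensity trend, a fit on the compared groups only, a replicate block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Leaving out libraries of groups not compared was added after the data were seen. Rescaling moved no median log2 change by more than 0.1 and no split of rises and falls by more than 10 percentage points. Lane and group are confounded in cells: the labels put MCF10A-D4 libraries on lane 6 and the other cell libraries on lane 5, while all xenograft libraries were on lane 6. No 2 libraries of a group matched within sampling noise (chi-square per degree of freedom of 3.56 or more).

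The procedure was tested on counts simulated from the real means, library sizes and dispersions, with 200 genes changed. For MCFDCIS-D4 against MCFDCIS cells (13430 genes), 23.9% of genes changed 1.5-fold, 59.7% changed 2-fold and 90.9% changed 4-fold were recovered, with 5 false calls among 121. For Mix against MCFDCIS tumours at W2 (15507 genes) the shares were 49.3%, 77.6% and 92.4%, with 6 false calls among 152. A list raised 1.5-fold was called in 9 of 9 simulated comparisons, and 1 of 294 other lists was called. Genes were simulated independently of each other, so these counts say nothing about false list calls where members move together. In the interaction between the cell lines the estimated correlation of the mitotic genes was 0.985. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.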

Results

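Total RNA with ribosomal RNA removed was sequenced from 12 cell culture and 15 xenograft libraries, with 3 libraries in each of 9 groups. MCF10A is an immortalised, non-tumorigenic human breast epithelial line, and MCFDCIS is a derivative of its lineage that forms lesions resembling ductal carcinoma in situ in mice. The series title ties the D4 lines to AIB1Δ4, a shortened isoform of the nuclear receptor coactivator AIB1, which NCOA3 encodes. Cell libraries held 25022960 to 37011458 reads over the listed genes and xenograft libraries 18839251 to 30166771. Levels are mean CPM ± SD over n = 3 libraries, and log2 changes are on the log2(CPM + 0.5) scale with the SE after ±.

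NCOA3 (chromosome 20, 46130631 to 46285621, GRCh37) stood at 162 ± 9.70 CPM in MCF10A, 245 ± 18.4 in MCF10A-D4, 65.3 ± 7.82 in MCFDCIS and 62.7 ± 1.5 in MCFDCIS-D4 cells. It rose in MCF10A-D4 against MCF10A cells by 0.59 ± 0.09 log2 units (limma, adjusted p = 0.000185). Its change in MCFDCIS-D4 against MCFDCIS was -0.05 ± 0.09 in cells (adjusted p = 0.796) and 0.17 ± 0.06 in W5 tumours (adjusted p = 0.067). The tumour value passed without MCFDCIS-D4 W5 replicate 1 (adjusted p = 0.0291) or MCFDCIS W2 replicate 1 (adjusted p = 0.0452). A value for the whole gene cannot show whether an exon is missing, so it does not check the D4 labels.

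**Figure D1:**
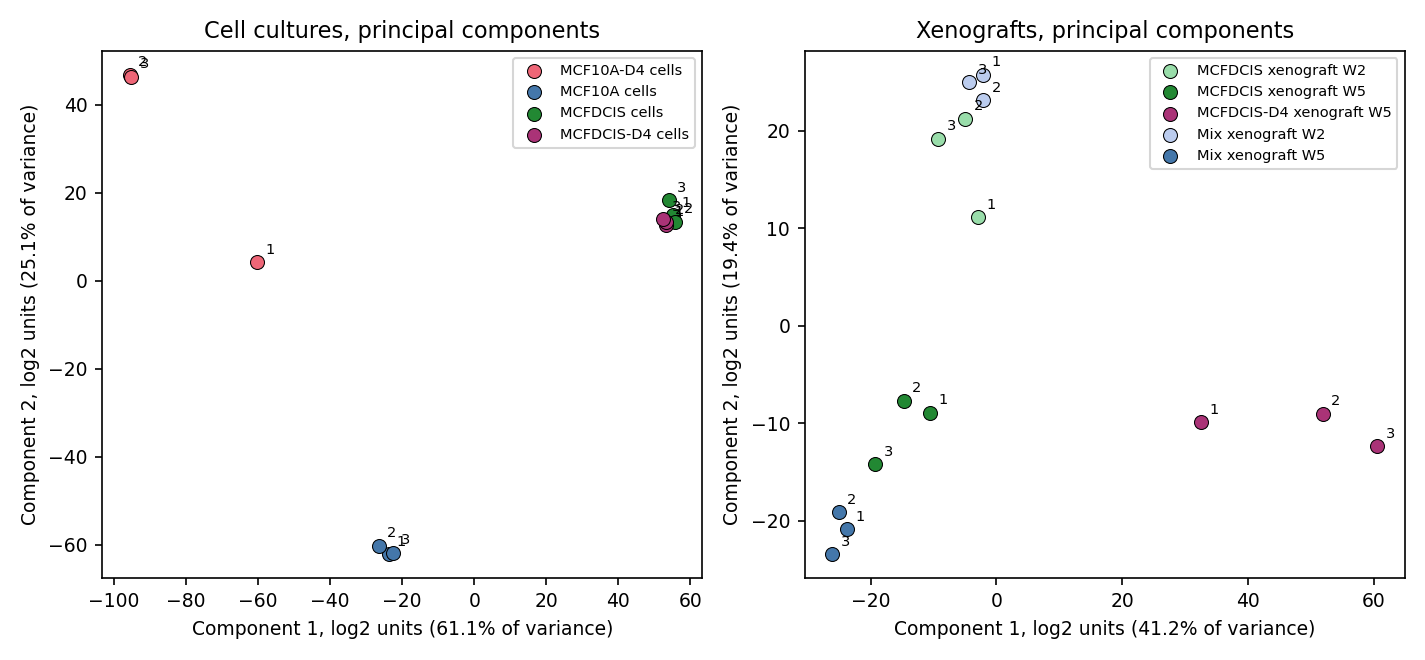
Principal components of log2(CPM + 0.5) in cell cultures (left) and xenografts (right), with both axes in log2 units; each point is 1 library, numbered by replicate and coloured by group. In cells the first component held 61.1% of the variance and in xenografts 41.2%.

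MCFDCIS-D4 was compared with MCFDCIS first in cultured cells. With a single D4 line in this background, D4 cannot be separated from other differences between the lines. In MCFDCIS-D4 cells 12 of 26 squamous differentiation genes and 11 of 29 protease and invasion genes rose, and 32 of 48 nuclear-encoded respiratory chain genes fell. None of these lists passed as a group with an estimated correlation (adjusted p = 0.466, 0.105 and 0.143). That correlation was estimated over all cell libraries, MCF10A-D4 replicate 1 included, and not again without that library. SERPINB2, an inhibitor of plasminogen activators (chromosome 18, 61538926 to 61571122), rose from 2.00 ± 0.49 to 57.4 ± 3.37 CPM, a log2 change of 4.55 ± 0.54 (adjusted p = 0.000391). CDH13, a cadherin anchored to the membrane by a lipid (chromosome 16, 82660570 to 83834245), fell from 28.2 ± 1.09 to 0.173 ± 0.020 CPM, a log2 change of -5.41 ± 0.07 (adjusted p = 4.6e-12). In all, 1704 of 13597 genes were called, of which 804 rose and 900 fell, and 131 rose and 163 fell at least 2-fold.

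Of 26 squamous differentiation genes, 12 rose, 2 fell and 12 did neither, and 17 rose and 2 fell when adjusted over the list alone. The list was higher as a group (camera, adjusted p = 3.57e-06; adjusted p = 0.466 with an estimated correlation). IVL, a precursor of the cornified envelope, rose from 2.82 ± 0.58 to 32.5 ± 3.19 CPM, and KRT6A from 2192 ± 107 to 5700 ± 119 CPM, while SERPINB3 fell from 49.8 ± 6.94 to 21.0 ± 1.39 CPM. The envelope gene SPRR3 rose from 0.127 ± 0.047 to 10.9 ± 1.81 CPM. SPRR2A stood at 33.9 ± 4.41 against 2.85 ± 1.14 CPM (adjusted p = 0.0257), but its call was lost without any 1 of the 6 compared libraries, with adjusted p of 0.0565, 0.0895 and 0.0837 without MCFDCIS replicate 1, 2 or 3 and of 0.0855, 0.0821 and 0.0709 without MCFDCIS-D4 replicate 1, 2 or 3. The basal keratin KRT14 rose from 42.1 ± 5.34 to 284 ± 15.6 CPM, and the adhesion protein CEACAM6 from 3.51 ± 1.17 to 48.4 ± 0.85 CPM. Of 29 protease and invasion genes, 11 rose and 2 fell, and the same numbers passed when adjusted over the list alone (adjusted p = 0.00324; adjusted p = 0.105 with an estimated correlation). They include the lysosomal protease CTSV, which rose from 87.1 ± 6.51 to 562 ± 3.26 CPM, and PLAU, the urokinase plasminogen activator, which rose from 18.0 ± 1.77 to 53.9 ± 0.71 CPM. MMP10, a matrix metalloprotease, rose from 0.451 ± 0.047 to 5.71 ± 0.62 CPM.

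Of 48 nuclear-encoded oxidative phosphorylation genes, 32 fell and 16 did neither, and 45 fell when adjusted over the list alone (adjusted p = 1.6e-21; adjusted p = 0.143 with an estimated correlation). Their median log2 change was -0.37. NDUFB9, a subunit of complex I, fell from 137 ± 4.52 to 82.4 ± 1.91 CPM, and SDHA from 168 ± 6.44 to 118 ± 2.59 CPM. Of 27 NF-kB and inflammatory cytokine genes, 7 rose and 2 fell, with 9 and 2 when adjusted over the list alone (adjusted p = 0.00367; adjusted p = 0.466 with an estimated correlation). IL1B rose from 17.9 ± 3.48 to 102 ± 3.03 CPM and IL1A from 129 ± 15.3 to 500 ± 17.3 CPM, while the chemokine CCL20 fell from 91.1 ± 4.48 to 56.5 ± 1.63 CPM. Of 24 cholesterol synthesis genes, 5 fell and 19 did neither, with 7 falling when adjusted over the list alone (adjusted p = 0.000433; adjusted p = 0.762 with an estimated correlation). Among other genes with the largest falls were IGFBP2, an insulin-like growth factor binding protein, from 50.4 ± 5.18 to 2.53 ± 0.66 CPM, the neurotrophin receptor NGFR from 88.0 ± 18.9 to 5.37 ± 0.61 CPM, the imprinted RNA H19 from 28.5 ± 1.99 to 1.6 ± 0.21 CPM, and TGFB2 from 27.9 ± 2.24 to 4.06 ± 0.72 CPM. SLC16A5 fell from 7.12 ± 0.75 to 0.510 ± 0.356 CPM and ARSD from 6.85 ± 1.26 to 0.0671 ± 0.116 CPM. The count of 1704 was lower with 2 libraries in a compared group: it was 1006, 1036 and 962 without MCFDCIS replicate 1, 2 or 3, and 959, 936 and 951 without MCFDCIS-D4 replicate 1, 2 or 3. It was 5003 without MCF10A-D4 replicate 1, a library of a group not compared here, and 5185 when only the 2 compared groups entered the fit, so it depended on the spread shared with that library.

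**Figure D2:**
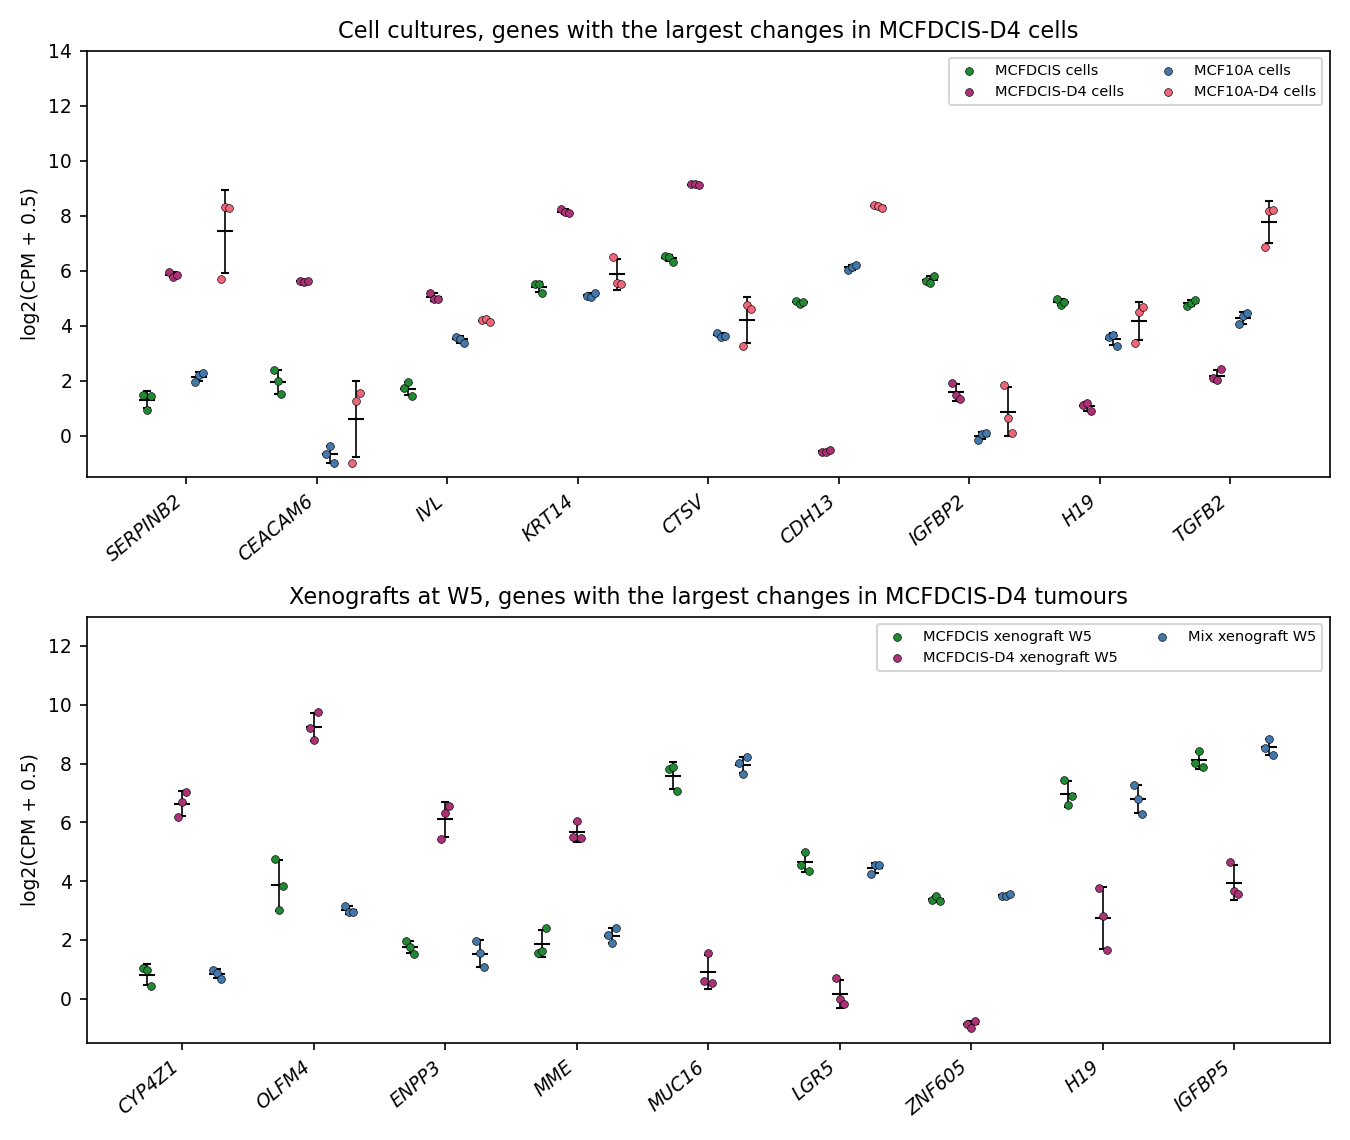
Levels as log2(CPM + 0.5) of genes with large changes, in cell cultures (top) and W5 xenografts (bottom); each point is 1 library, the bar is the mean and the whiskers are 1 SD of n = 3. SERPINB2 and IVL are higher and CDH13 lower in MCFDCIS-D4 than in MCFDCIS cells, and MUC16 is low in MCFDCIS-D4 tumours (1.47 CPM) and high in Mix tumours (250 CPM).

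The same comparison was made in MCF10A, again with a single D4 line. MCF10A-D4 cells had lower levels of every measured mitotic and DNA replication gene of the lists and higher levels of most matrix and inflammatory genes of the lists. PAPPA, a metalloprotease that cleaves insulin-like growth factor binding proteins (chromosome 9, 118916070 to 119164600), rose from 2.61 ± 0.82 to 519 ± 205 CPM, a log2 change of 7.33 ± 0.29 (adjusted p = 2.15e-08). The long non-coding RNA CCAT1 fell from 29.0 ± 3.05 to 0.0329 ± 0.057 CPM, a log2 change of -5.79 ± 0.13 (adjusted p = 4.06e-10). In all 8627 genes were called, with 4639 rising and 3988 falling, and 1717 and 1099 of these changed at least 2-fold.

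All 38 mitotic genes and all 40 DNA replication genes fell, with the same numbers when adjusted over the list alone, at median log2 changes of -2.73 and -2.11 (camera, adjusted p = 8.69e-12 and 6.97e-14; adjusted p = 0.455 and 0.438 with an estimated correlation). CDK1, the mitotic kinase, fell from 334 ± 33.3 to 45.7 ± 38.8 CPM, and MCM4, a subunit of the replicative helicase, from 380 ± 4.65 to 96.1 ± 26.9 CPM. MYBL2, a transcription factor of the cell cycle, fell from 189 ± 12.9 to 23.3 ± 22.9 CPM. Of 48 replication-dependent histone genes 47 fell, also when adjusted over the list alone (adjusted p = 1.63e-16; adjusted p = 0.387 with an estimated correlation). Of 30 p53 target genes 23 rose and 2 fell, with the same numbers when adjusted over the list alone (adjusted p = 8.79e-06; adjusted p = 0.0363 with an estimated correlation). GDF15 rose from 1.39 ± 0.21 to 58 ± 5.62 CPM, and MDM2, the ubiquitin ligase of p53, from 167 ± 6.13 to 433 ± 26.4 CPM.

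Of 24 fibrillar collagen and matrix genes 18 rose and 1 fell, with 19 and 1 when adjusted over the list alone (adjusted p = 1.51e-06; adjusted p = 0.025 with an estimated correlation). The collagen genes COL5A3 and COL6A1 rose from 0.691 ± 0.412 to 128 ± 13.9 CPM and from 11.1 ± 1.61 to 766 ± 393 CPM. Of 29 protease and invasion genes 16 rose and 3 fell, with the same numbers when adjusted over the list alone (adjusted p = 0.00186; adjusted p = 0.0499 with an estimated correlation). Of 27 NF-kB and inflammatory cytokine genes 22 rose and none fell, with 22 when adjusted over the list alone (adjusted p = 1.04e-07; adjusted p = 0.0788 with an estimated correlation), and IL1B rose from 1.69 ± 0.24 to 109 ± 58.7 CPM. Of 37 interferon response genes 27 rose and 2 fell, with the same numbers when adjusted over the list alone (adjusted p = 2.78e-05; adjusted p = 0.163 with an estimated correlation), among them IFITM3, from 48.7 ± 0.52 to 239 ± 42 CPM. The complement proteases C1R and C1S rose from 1.18 ± 0.15 to 224 ± 136 CPM and from 0.762 ± 0.074 to 143 ± 98.0 CPM, and the receptor NOTCH3 from 3.15 ± 0.58 to 281 ± 175 CPM. FBXO32 rose from 2.60 ± 0.22 to 320 ± 132 CPM and GALNT15 from 1.07 ± 0.45 to 176 ± 135 CPM. SCNN1G and SCNN1B, subunits of the epithelial sodium channel, fell from 51.6 ± 2.05 to 0.792 ± 0.692 CPM and from 7.46 ± 0.27 to 0.0879 ± 0.0803 CPM. The oestrogen sulfotransferase SULT1E1 fell from 16.8 ± 2.16 to 0.0350 ± 0.0605 CPM, and S100P from 264 ± 28.1 to 10.9 ± 8.07 CPM.

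Markers of another cell type moved with the matrix genes: of 7 fibroblast markers 5 rose and none fell, with 6 when adjusted over the list alone (adjusted p = 0.0271; adjusted p = 0.149 with an estimated correlation), and the call was lost without MCF10A-D4 replicate 1 (adjusted p = 0.0762). The matrix proteoglycan DCN stood at 3946 ± 2670 CPM against 107 ± 11.3. Lane and group cannot be separated in this comparison, and the mitochondrial ribosomal RNA RNR2 was at 3237 to 16769 CPM in the MCF10A-D4 libraries against 65.8 to 233 CPM in MCF10A. MCF10A-D4 replicate 1 stood apart, with a median of 6.31 log2 units over the mitotic genes against 4.31 and 4.35 in replicates 2 and 3, and 7.59 to 7.66 in MCF10A.

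**Figure D3:**
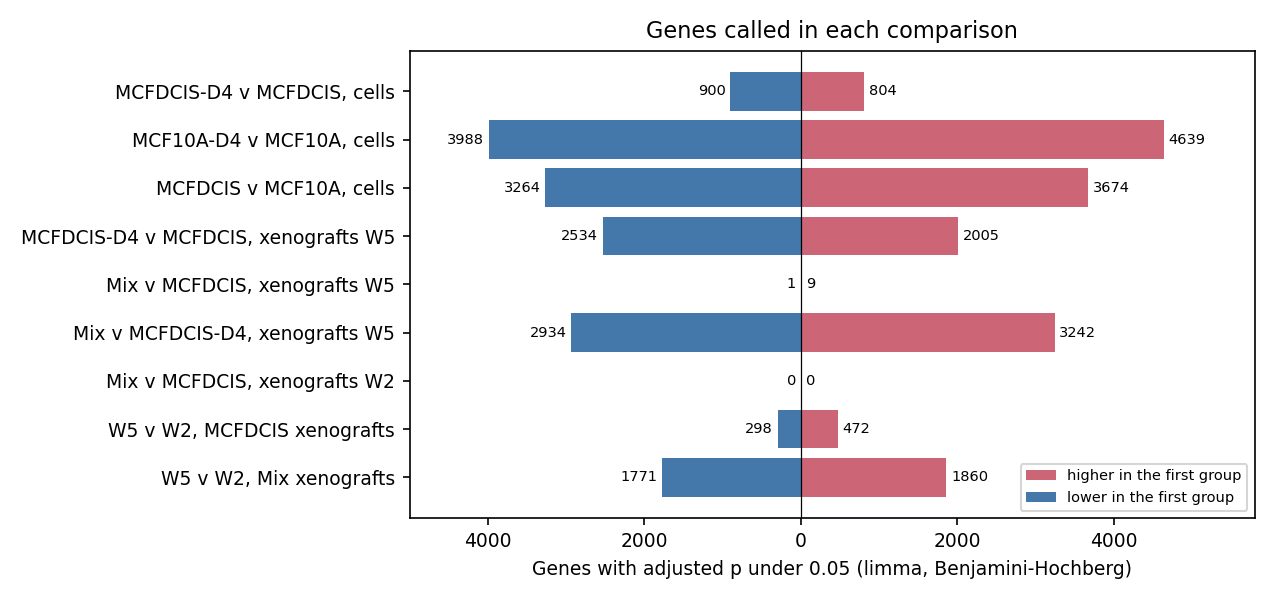
Number of genes with adjusted p under 0.05 (limma, Benjamini-Hochberg) in each comparison; bars to the right count genes higher in the first group named and bars to the left genes lower in it. Counts run from 0 for Mix against MCFDCIS tumours at W2 to 4639 rising and 3988 falling for MCF10A-D4 against MCF10A cells.

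The D4 effects in the cell lines had little in common across genes. Over 13597 genes the log2 changes in MCFDCIS and in MCF10A correlated with Pearson r of -0.0052 and Spearman rho of 0.0223, and 51.4% of genes had the same sign. These are across genes, which are not independent replicates. In both lines 351 genes rose, against 274 for independent lists, and 292 fell, against 264, while 200 rose in MCFDCIS and fell in MCF10A and 346 did the opposite. If the exchange of the MCF10A and MCF10A-D4 titles were wrong, every change in MCF10A would turn its sign, these counts would change places, and the interaction below would be a sum of effects. The change itself differed between the lines for 6924 genes (interaction, limma). Among the cells only MCF10A-D4 was on lane 6, so lane cannot be separated from this difference. Nor can differences other than D4 between each D4 line and its parent. CDH13 had a log2 change of -5.41 in MCFDCIS and of 2.22 in MCF10A, a difference of -7.63 ± 0.11 (adjusted p = 4.77e-12), and SULF1, a heparan sulfate endosulfatase, of -2.69 and 5.50, a difference of -8.19 ± 0.21 (adjusted p = 1.5e-09).

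MCFDCIS and MCF10A cells were compared as the parents of the D4 lines, under the current titles (with the earlier ones the second group would be MCF10A-D4). MCFDCIS cells had higher levels of many inflammatory genes and lower levels of many mesenchymal and YAP/TEAD target genes of the lists, as well as higher levels of some squamous and basal genes. None of these lists passed as a group with an estimated correlation (adjusted p = 0.17 to 0.71). The cadherin CDH19 (chromosome 18, 64168320 to 64271375) rose from 0.218 ± 0.136 to 135 ± 9.75 CPM, a log2 change of 7.57 ± 0.14 (adjusted p = 3.19e-11). The actin crosslinker FLNA (chromosome X, 153576892 to 153603002) fell from 2844 ± 291 to 10.6 ± 0.59 CPM, a log2 change of -8.00 ± 0.11 (adjusted p = 3.58e-12). In all 6938 genes were called, 3674 rising and 3264 falling.

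Other large rises were those of the calcium-binding protein CALB2, from 0.0458 ± 0.0794 to 94.6 ± 3.03 CPM, the matricellular protein SPARC, from 0.222 ± 0.103 to 96.0 ± 4.71 CPM, and the protease inhibitor SERPINA3, from 18.2 ± 1.07 to 2229 ± 113 CPM. BST2, LCN2 and RASAL1 rose by 6.96 ± 0.25, 6.77 ± 0.69 and 6.52 ± 0.15 log2 units. The metallothionein MT1E fell from 307 ± 30.3 to 1.49 ± 0.50 CPM, mesothelin (MSLN) from 105 ± 1.75 to 0.246 ± 0.169 CPM, and the actin-bundling protein LCP1 from 251 ± 10.5 to 1.48 ± 0.33 CPM. POSTN, MAOA and AKAP12 fell to 0.239 ± 0.022, 0.999 ± 0.157 and 12.4 ± 1.33 CPM. NCOA3 fell by 1.31 ± 0.09 log2 units (adjusted p = 5.29e-07). Of 27 NF-kB and inflammatory cytokine genes 21 rose and 1 fell, with the same numbers when adjusted over the list alone (adjusted p = 1.39e-07; adjusted p = 0.17 with an estimated correlation), among them CXCL8, from 10.5 ± 2.14 to 330 ± 39 CPM. Of 26 squamous differentiation genes 13 rose and 1 fell, with 14 and 1 when adjusted over the list alone (adjusted p = 0.00674; adjusted p = 0.71 with an estimated correlation), and of 22 basal and myoepithelial markers 11 rose and 2 fell, with the same numbers when adjusted over the list alone (adjusted p = 0.0391; adjusted p = 0.71 with an estimated correlation). KRT6B rose from 173 ± 15.5 to 2714 ± 33.4 CPM and KRT15 from 23 ± 1.25 to 1307 ± 178 CPM. Of 20 mesenchymal genes 5 rose and 11 fell, with the same numbers when adjusted over the list alone (adjusted p = 0.0391; adjusted p = 0.365 with an estimated correlation), and fibronectin (FN1) fell from 1538 ± 99 to 82.5 ± 11.9 CPM. Of 21 YAP/TEAD target genes 3 rose and 13 fell, with the same numbers when adjusted over the list alone (adjusted p = 0.0042; adjusted p = 0.365 with an estimated correlation).

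In tumours at W5, MCFDCIS-D4 was compared with MCFDCIS. In MCFDCIS-D4 tumours most hypoxia, glycolysis, mitotic and DNA replication genes of the lists fell, and several luminal mammary markers rose. None of these lists passed as a group with an estimated correlation (adjusted p = 0.299 to 0.553). CYP4Z1, a cytochrome P450 enriched in mammary tissue (chromosome 1, 47532903 to 47583990), rose from 1.30 ± 0.40 to 102 ± 29.3 CPM, a log2 change of 5.81 ± 0.24 (adjusted p = 1.73e-10). The mucin MUC16 (chromosome 19, 8959520 to 9121066) fell from 199 ± 57.6 to 1.47 ± 0.86 CPM, a log2 change of -6.69 ± 0.32 (adjusted p = 5.43e-10). In all 4539 of 15677 genes were called, 2005 rising and 2534 falling, and 288 and 558 of these changed at least 2-fold.

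Of 30 hypoxia genes 26 fell, 1 rose and 3 did neither, with 28 and 1 when adjusted over the list alone (camera, adjusted p = 1.43e-14; adjusted p = 0.299 with an estimated correlation). Carbonic anhydrase CA9 fell from 36.7 ± 6.91 to 3.72 ± 0.37 CPM and NDRG1 from 967 ± 293 to 149 ± 44.2 CPM. Of 19 glycolysis genes 15 fell, and 17 when adjusted over the list alone (adjusted p = 1.08e-11; adjusted p = 0.299 with an estimated correlation), among them the lactate transporter SLC16A3, from 215 ± 12.5 to 71.5 ± 9.06 CPM. Of 38 mitotic genes 36 fell, and 37 when adjusted over the list alone (adjusted p = 5.13e-16; adjusted p = 0.519 with an estimated correlation), with a median log2 change of -0.78. The proliferation marker MKI67 fell from 213 ± 19.2 to 85.6 ± 20.1 CPM. Of 40 DNA replication genes 33 fell, and 36 when adjusted over the list alone (adjusted p = 2.16e-11; adjusted p = 0.519 with an estimated correlation). Of 22 mesenchymal genes 13 fell and none rose, with 14 falling when adjusted over the list alone (adjusted p = 8.6e-06; adjusted p = 0.519 with an estimated correlation), and FN1 fell from 6443 ± 898 to 1140 ± 961 CPM. Of 34 protease and invasion genes 18 fell and 3 rose, with 19 and 3 when adjusted over the list alone (adjusted p = 1.92e-05; adjusted p = 0.519 with an estimated correlation), and MMP9 fell from 221 ± 163 to 32.0 ± 45.3 CPM.

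Of 22 luminal mammary markers 10 rose and 5 fell, with the same numbers when adjusted over the list alone (adjusted p = 0.0341; adjusted p = 0.553 with an estimated correlation), and the call of the list was lost without MCFDCIS-D4 replicate 3 (adjusted p = 0.238). The oestrogen receptor gene ESR1 rose from 14.2 ± 4.76 to 49.5 ± 16.6 CPM, and ELF5, a transcription factor of the alveolar lineage, from 5.15 ± 1.28 to 33.0 ± 8.66 CPM. The secreted glycoprotein OLFM4 rose from 15.8 ± 9.49 to 632 ± 211 CPM, ENPP3 from 2.89 ± 0.49 to 71.9 ± 26.2 CPM, the polymeric immunoglobulin receptor PIGR from 0.692 ± 0.580 to 21.6 ± 8.22 CPM, the peptidase MME from 3.29 ± 1.30 to 51.4 ± 12.4 CPM, lactoferrin (LTF) from 3.44 ± 3.77 to 51.3 ± 37.5 CPM and IL33 from 0.686 ± 0.324 to 15.9 ± 8.24 CPM. ACTL8 rose from 0.306 ± 0.178 to 27.5 ± 32.4 CPM. LGR5, a receptor for R-spondins, fell from 24.9 ± 6.03 to 0.664 ± 0.405 CPM, H19 from 129 ± 40.1 to 7.45 ± 5.34 CPM, IGFBP5 from 279 ± 56.4 to 15.9 ± 7.46 CPM, ZNF605 from 10.0 ± 0.71 to 0.0482 ± 0.0468 CPM and KANK4 from 12.6 ± 2.14 to 0.647 ± 0.122 CPM.

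Markers of other cells were measured in the same tumours. Of 11 adipocyte markers 6 rose, 1 fell and 4 did neither, with the same numbers when adjusted over the list alone (adjusted p = 0.019; adjusted p = 0.553 with an estimated correlation), and PLIN1, a lipid droplet protein, rose from 1.34 ± 0.11 to 4.10 ± 0.53 CPM. That list's call was lost without MCFDCIS-D4 replicate 1 (adjusted p = 0.0604) and with a mean of at least 5 CPM (adjusted p = 0.54). Of 17 fibroblast markers 3 rose and 6 fell, with 3 and 7 when adjusted over the list alone (adjusted p = 0.46). Of 13 macrophage and myeloid markers 1 rose, also when adjusted over the list alone (adjusted p = 0.46), and of 16 endothelial markers 2 rose and 2 fell, with 3 and 2 when adjusted over the list alone (adjusted p = 0.893). Of 11 skeletal muscle markers 1 fell, also when adjusted over the list alone (adjusted p = 0.772). None of the 3 erythroid genes passed limma, also when adjusted over the list alone (adjusted p = 0.465). Across 13347 genes tested in both tables, the D4 effect in tumours and that in cells correlated with r of 0.0337 and rho of 0.0672. In both, 135 genes rose, against 101 for independent lists, and 294 fell, against 153. In the other direction, 180 genes rose in cells and fell in tumours, and 101 fell in cells and rose in tumours. MCFDCIS-D4 cells and tumours carried different library names, so a difference between lines cannot be separated from one between culture and tumour. In the tumour comparison the number of called genes was 2974 when only the 2 compared groups entered the fit.

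**Figure D4:**
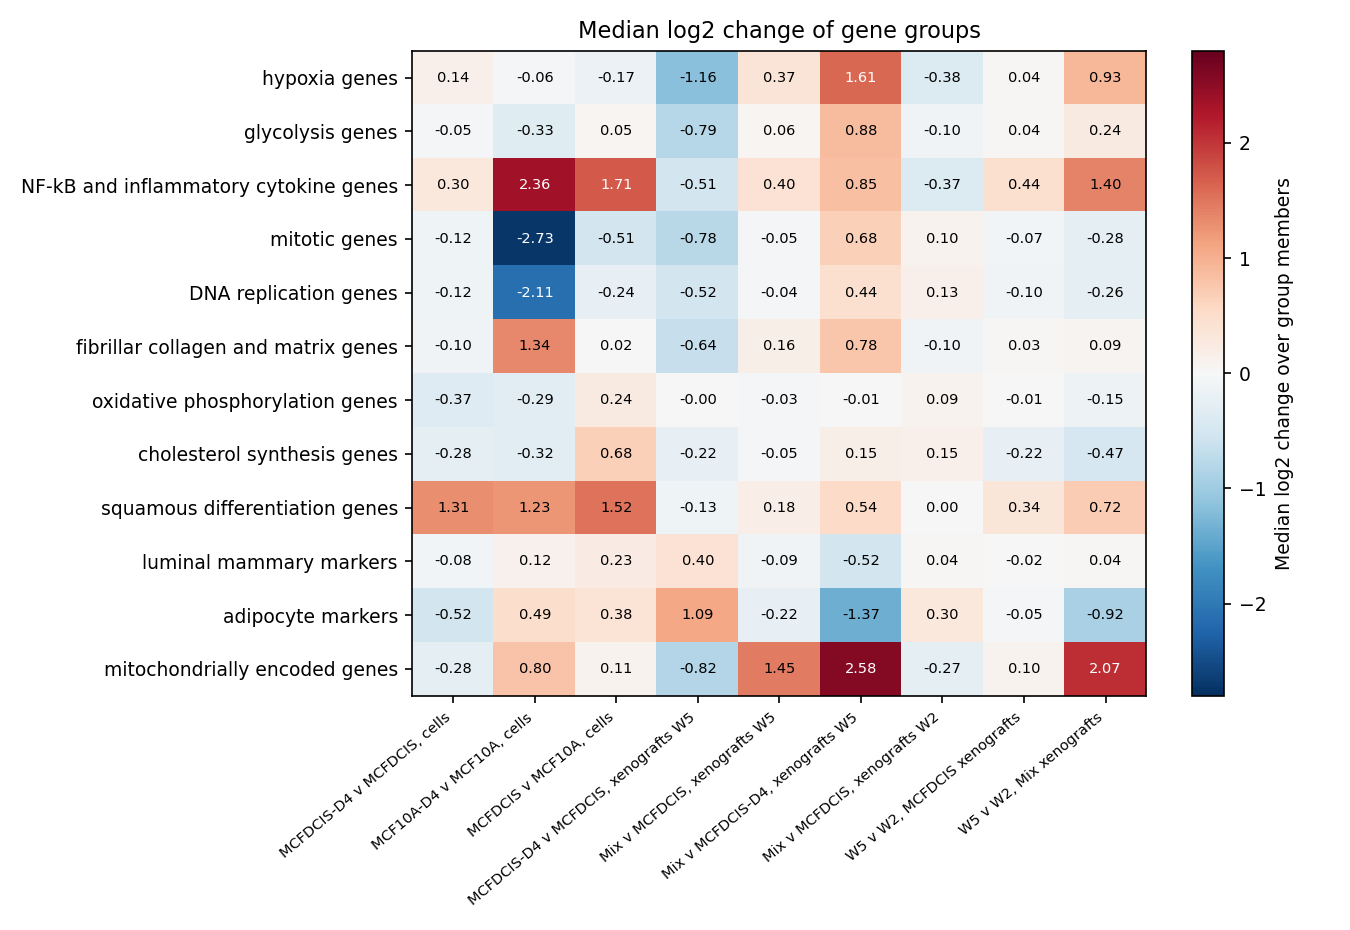
Median log2 change over the members of 12 gene groups (vertical axis) in 9 comparisons (horizontal axis), coloured from blue (lower in the first group named) to red (higher); the numbers are the medians and carry no test. Hypoxia genes had a median of -1.16 in MCFDCIS-D4 against MCFDCIS tumours and of 1.61 in Mix against MCFDCIS-D4 tumours.

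Tumours grown from a mixture of MCFDCIS and MCFDCIS-D4 cells were compared with each pure tumour at W5. Against MCFDCIS-D4 tumours, most hypoxia, glycolysis and mitotic genes of the lists rose in Mix tumours. None of these lists passed as a group with an estimated correlation (adjusted p = 0.312, 0.367 and 0.443). MUC16 rose to 250 ± 47.6 CPM, a log2 change of 7.05 ± 0.32 (adjusted p = 2.57e-10), and OLFM4 fell to 7.62 ± 0.72 CPM, a log2 change of -6.23 ± 0.30 (adjusted p = 4.38e-10). In all 6176 genes were called, 3242 rising and 2934 falling. IGFBP5 rose to 379 ± 71.8 CPM, MMP9 to 358 ± 47.7 CPM, LGR5 to 21.5 ± 2.62 CPM and ZNF605 to 10.9 ± 0.32 CPM, while CYP4Z1 fell to 1.30 ± 0.19 CPM, ENPP3 to 2.48 ± 0.92 CPM, PIGR to 0.707 ± 0.209 CPM and ACTL8 to 0.617 ± 0.405 CPM. Of 30 hypoxia genes 29 rose and 1 fell, with the same numbers when adjusted over the list alone (adjusted p = 5.44e-16; adjusted p = 0.312 with an estimated correlation). Of 19 glycolysis genes 15 rose, and 16 when adjusted over the list alone (adjusted p = 1.68e-10; adjusted p = 0.367 with an estimated correlation). Of 38 mitotic genes 36 rose, and 37 when adjusted over the list alone (adjusted p = 5.76e-12; adjusted p = 0.443 with an estimated correlation). Of 11 adipocyte markers 8 fell and 1 rose, with the same numbers when adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.489 with an estimated correlation), and this call was lost with a mean of at least 5 CPM (adjusted p = 0.476).

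Against MCFDCIS tumours at W5, 6 of 12 mitochondrially encoded genes rose in Mix tumours, with few other calls, and the list did not pass as a group with an estimated correlation (adjusted p = 0.321). ND6, a complex I subunit, rose from 10 ± 1.2 to 91.4 ± 43.5 CPM, a log2 change of 2.99 ± 0.32 (adjusted p = 0.000488), and ATP8, ND1, ND5 and ND2 rose by 2.44 ± 0.26, 2.17 ± 0.26, 2.05 ± 0.24 and 1.95 ± 0.24 log2 units. The mucin MUC2 rose from 0.458 ± 0.139 to 5.72 ± 1.38 CPM (adjusted p = 0.000968). Of 12 mitochondrially encoded genes 6 rose and none fell, with 10 rising when adjusted over the list alone (adjusted p = 1.06e-20; adjusted p = 0.321 with an estimated correlation). In all 10 genes were called, 9 rising and 1 falling. CYTB had a log2 change of 1.5 ± 0.26 (adjusted p = 0.0367) and the phosphatase gene PGP one of -0.45 ± 0.08 (adjusted p = 0.0355). The CYTB call was lost without MCFDCIS W5 replicate 1 or 2 (adjusted p = 0.366 and 0.227), without Mix W5 replicate 1 or 3 (0.142 and 0.302), and without 4 of the W2 libraries, MCFDCIS replicate 2 (0.0554) and Mix replicates 1, 2 and 3 (0.075, 0.0786 and 0.0782). The PGP call was lost without MCFDCIS W5 replicate 1 or 2 (0.298 and 0.147), without Mix W5 replicate 1, 2 or 3 (0.23, 0.0769 and 0.242), and without MCFDCIS W2 replicate 2 or 3 (0.0605 and 0.0536) or Mix W2 replicate 1, 2 or 3 (0.0737, 0.0636 and 0.0594). MUC6 and RYR2, which also rose, fall outside the rule for named genes and were chosen after their values were seen. The number of called genes was 6, 6 and 30 without MCFDCIS W5 replicate 1, 2 or 3, 5 without Mix W5 replicate 1 or 3, and 32 without MCFDCIS-D4 W5 replicate 1. edgeR called 9 genes and DESeq2 73, and 1646 had an unadjusted p under 0.05, where chance alone gives about 784.

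A score of the D4 change seen in cells was taken in the tumours over 279 genes. These had at least 1 log2 unit of change between the MCFDCIS-D4 and MCFDCIS cells. Each gene was set against its mean in MCFDCIS W5 tumours and signed by its direction in cells. The mean of the library medians at W5 was -0.00446 ± 0.0161 (SD, n = 3) in MCFDCIS, 0.0666 ± 0.0678 in MCFDCIS-D4 and 0.0374 ± 0.00312 in Mix tumours. Both differences from MCFDCIS had p = 0.1 in a two-sided exact permutation test, the smallest p that 3 libraries against 3 allow, and Mix against MCFDCIS-D4 had p = 0.8. Without MCFDCIS cell replicate 1 the MCFDCIS-D4 value changed sign, to -0.00768, and the W2 libraries lay at -0.179 to -0.109, further from the MCFDCIS W5 mean than the MCFDCIS-D4 mean did. With at least 2 log2 units of change in cells the values were 0.221 for MCFDCIS-D4 and 0.0586 for Mix tumours. The separation of the pure W5 tumours on this score thus depends on the genes taken, and the score cannot place the mixture. Its genes come from cells, where the D4 change correlated with that in tumours at r of only 0.0337. Other values put Mix W5 tumours on the MCFDCIS side: 10 genes were called against MCFDCIS and 6176 against MCFDCIS-D4 tumours. On the first principal component Mix W5 libraries lay at -26.1 to -23.8, MCFDCIS W5 at -19.3 to -10.5 and MCFDCIS-D4 W5 at 32.6 to 60.6.

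At W2, Mix tumours and MCFDCIS tumours differed in no gene by limma. No gene was called by limma or edgeR and 1 by DESeq2, and 720 had an unadjusted p under 0.05, where chance alone gives about 784. In simulated counts 77.6% of genes changed 2-fold were recovered in this comparison. As a group the 30 hypoxia genes were lower in Mix, with a median log2 change of -0.38, 0 called members and 13 falling when adjusted over the list alone (camera, adjusted p = 4.57e-19; adjusted p = 0.324 with an estimated correlation). The 29 NF-kB and inflammatory cytokine genes had a median of -0.37, with 0 called members, also when adjusted over the list alone (adjusted p = 5.06e-07; adjusted p = 0.515 with an estimated correlation). The mitochondrial ribosomal RNA RNR2 was at 7396 CPM in MCFDCIS W2 replicate 1, against 772 and 854 CPM in the other libraries of that group.

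Growth from W2 to W5 was followed in MCFDCIS and in Mix tumours. In MCFDCIS tumours the kallikreins KLK6 and KLK11 rose, with 6 of 34 protease genes, and 16 of 74 ribosomal protein genes fell. Neither list passed as a group with an estimated correlation (adjusted p = 0.471 and 0.42). KLK6, a secreted serine protease (chromosome 19, 51461887 to 51472929), rose from 12.7 ± 4.02 to 125 ± 14.8 CPM, a log2 change of 3.29 ± 0.22 (adjusted p = 3.61e-07). CYP4Z1 fell from 20.8 ± 6 to 1.30 ± 0.40 CPM, a log2 change of -3.55 ± 0.24 (adjusted p = 3.61e-07). In all 770 genes were called, 472 rising and 298 falling. KLK11 rose from 5.56 ± 3.85 to 25.7 ± 0.14 CPM, the cation channel TRPM8 from 3.42 ± 0.52 to 14.3 ± 1.01 CPM and NELL2 from 0.540 ± 0.074 to 8.89 ± 4.90 CPM. SEMA3G, a secreted semaphorin, fell from 27.0 ± 2.28 to 4.03 ± 1.43 CPM, CPLX3 from 27.0 ± 3.33 to 5.37 ± 1.09 CPM and CRISP3 from 8.57 ± 8.68 to 0.238 ± 0.155 CPM. MMP12 (log2 change 2.37 ± 0.60, adjusted p = 0.0287) lost its call without MCFDCIS W2 replicate 1 or 2 (adjusted p = 0.0803 and 0.113) and without W5 replicate 1 or 2 (0.141 and 0.0893). DCD (-2.74 ± 0.64, adjusted p = 0.0196) lost its call without W5 replicate 2 or 3 (adjusted p = 0.0586 and 0.0832). Of 74 cytosolic ribosomal protein genes 16 fell, and 61 when adjusted over the list alone (adjusted p = 5.26e-24; adjusted p = 0.42 with an estimated correlation), with a median log2 change of -0.25. Of 34 protease and invasion genes 6 rose, and 12 when adjusted over the list alone (adjusted p = 8.73e-06; adjusted p = 0.471 with an estimated correlation), among them MMP7, from 113 ± 12 to 419 ± 62.2 CPM. The number of called genes was 387 without MCFDCIS W2 replicate 2, 457 and 447 without MCFDCIS W5 replicate 1 or 2, and 1312 without MCFDCIS-D4 W5 replicate 1.

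In Mix tumours most hypoxia and inflammatory genes of the lists rose from W2 to W5, and most cholesterol synthesis and ribosomal protein genes fell. Of 30 hypoxia genes 26 rose and none fell, with 26 rising and 2 falling when adjusted over the list alone (adjusted p = 1.52e-13; adjusted p = 0.212 with an estimated correlation), and the glucose transporter SLC2A1 rose from 154 ± 18.9 to 399 ± 17.4 CPM. Of 29 NF-kB and inflammatory cytokine genes 24 rose, and 26 when adjusted over the list alone (adjusted p = 3.09e-13; adjusted p = 0.212 with an estimated correlation). Of 24 cholesterol synthesis genes 20 fell, and 21 when adjusted over the list alone (adjusted p = 2.86e-10; adjusted p = 0.212 with an estimated correlation), and of 74 ribosomal protein genes 64 fell, and 72 when adjusted over the list alone (adjusted p = 5.07e-19; adjusted p = 0.355 with an estimated correlation). In all 3631 genes were called, 1860 rising and 1771 falling.

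Single genes with the largest changes in Mix tumours were the collagenase MMP1, which rose from 0.600 ± 0.304 to 12.8 ± 2.90 CPM, NELL2, from 0.944 ± 0.358 to 14.3 ± 4.88 CPM, KLK6, from 13.2 ± 1.70 to 111 ± 2.19 CPM, and ND6, from 9.55 ± 2.55 to 91.4 ± 43.5 CPM. IL24 had a log2 change of 3.06 ± 0.82 (adjusted p = 0.0137), a call that was lost without Mix W5 replicate 1 (adjusted p = 0.0543). The adjacent genes LMAN1L and CPLX3 on chromosome 15 fell from 35.9 ± 2.84 to 3.41 ± 1.75 CPM and from 28.3 ± 5.37 to 2.92 ± 0.77 CPM. CYP4Z1 fell from 14.6 ± 3.00 to 1.30 ± 0.19 CPM, SEMA3G from 28.2 ± 3.86 to 3.12 ± 0.78 CPM and OLFM4 from 60.8 ± 3.00 to 7.62 ± 0.72 CPM. NCOA3 rose by 0.40 ± 0.06 log2 units (adjusted p = 0.000452). Of 11 adipocyte markers 5 fell, and 6 when adjusted over the list alone (adjusted p = 0.00154; adjusted p = 0.368 with an estimated correlation). The number of called genes was 2336 and 2378 without Mix W2 replicate 1 or 3, and 2273 without Mix W5 replicate 3. The change over time differed between Mix and MCFDCIS tumours for 6 genes (interaction, limma), with 6 by edgeR and 79 by DESeq2. At an unadjusted p under 0.05 there were 1698, where chance alone gives about 784. The limma count of 6 became 40 without MCFDCIS W5 replicate 3, 53 without MCFDCIS-D4 W5 replicate 1 and 1 with no intensity trend.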

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

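The tests that weigh explanations for the 3 patterns below were chosen after the results were seen, as was the sorting of splits by the libraries they reverse; the counts over other splits of the samples were planned before.

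By a test of the difference itself, the D4 effect differed between the lines for 6924 genes. Neither lane nor differences other than D4 between each D4 line and its parent can be separated from this. Of the genes named for that comparison, NCOA3 differed by -0.643 log2 units (MCFDCIS minus MCF10A), CCAT1 by 5.95, GDA by 5.65, SCNN1G by 5.10, PSCA by 4.49, PAPPA by -8.23, SULF1 by -8.19, CDH13 by -7.63 and NOTCH3 by -7.32. By median over a gene group, the difference was 2.28 for replication-dependent histone genes, 1.97 for DNA replication genes, 2.59 for mitotic genes and -1.59 for fibrillar collagen and matrix genes. The difference passed limma upwards in 46 of 48, 39 of 40 and 38 of 38 genes of the first lists (47, 39 and 38 when adjusted over the list alone), and in 2 upwards and 18 downwards of 24 matrix genes (the same numbers when adjusted over the list alone). With an estimated correlation, of these 4 lists only the matrix genes passed (adjusted p = 0.0152), and the others had adjusted p of 0.428, 0.497 and 0.532. Of 100 splits of the 12 cell libraries drawn within the lines, 2 gave as many genes, the real one included. The highest of the other splits gave 7069 genes and reverses the labels in 1 line, which adds the effects, while splits that mix the groups hold the D4 effects in their spread, so the splits decide nothing about chance here.

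The change from W2 to W5 differed between Mix and MCFDCIS tumours for 6 genes, and for 1 with no intensity trend. ND6 differed by 3.23 log2 units (Mix minus MCFDCIS), ATP8 by 3.06, ND1 by 2.71, ND2 by 2.44 and PGP by -0.699. The PGP call was lost without any 1 of MCFDCIS W2 replicate 3, MCFDCIS W5 replicates 1 and 2, Mix W2 replicates 1 and 2 and Mix W5 replicates 1 and 3 (adjusted p = 0.0516 to 0.0878). By median over a gene group, the difference was 0.846 for hypoxia genes, 1.78 for mitochondrially encoded genes, 0.685 for NF-kB and inflammatory cytokine genes and 0.314 for MAPK and AP-1 response genes. Of the mitochondrially encoded genes 5 of 12 passed limma and of the other lists 0 of 30, 29 and 31 (22, 2 and 1 when adjusted over the list alone), and with an estimated correlation no list of these passed (adjusted p = 0.231, 0.231, 0.524 and 0.263). Of 100 splits 12 gave as many genes, the real one included. The highest of the other splits gave 4025 and reverses W2 and W5 in 1 tumour composition, which adds the changes over time by construction. Of the 54 other splits that do not reverse most libraries of 1 composition, 6 gave at least as many genes as the real one, with a highest count of 169. Such splits also hold the changes over time in their spread or their contrast, so the splits decide nothing about chance here either.

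For the comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real split alone reached its count, 1 of 10 splits, for D4 in MCFDCIS cells (1704, highest other 0), D4 in MCF10A cells (8627, 0), MCFDCIS against MCF10A cells (6938, 0), D4 in W5 tumours (4539, 17), Mix against MCFDCIS at W5 (10, 0), Mix against MCFDCIS-D4 (6176, 0), and W5 against W2 in MCFDCIS (770, 0) and in Mix (3631, 0). For Mix against MCFDCIS at W2 all 10 splits gave 0 genes.

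MCF10A-D4 replicate 1 correlated with replicates 2 and 3 at r of 0.941 and 0.939 across genes, against 0.997 between those. MCF10A cells mixed into that library would place all genes at the same share of the way from MCF10A to replicates 2 and 3, but the median place was 26.2% for 136 genes higher and 73.5% for 96 genes lower in replicates 2 and 3, a gap of 47.3 percentage points that argues against it. MCFDCIS cells are argued against by a median of 2.65% of the MCFDCIS level over 6 genes of those cells, with CALB2 at 0.139% and NGFR at 13.5%. A larger part of ribosomal and small RNA would leave protein-coding genes in their ratios, but the SD of their log2 ratios was 0.735 over 10186 genes, against 0.129 between replicates 2 and 3. A different state of that culture may stand behind the difference, which was not tested, and lane cannot be told apart from group for all 3 libraries.

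In Mix tumours at W5, 6 of 12 mitochondrially encoded genes were higher than in MCFDCIS tumours, and the list did not pass as a group with an estimated correlation (adjusted p = 0.321). A common rise of all 12 is argued against by a gap of 2.89 ± 0.344 (SE) log2 units between ND6 and COX3, and a rise of the whole respiratory chain by a median of -0.027 ± 0.0659 (SD over genes) in 48 nuclear-encoded genes, against 1.45. Mitochondrial DNA carried into the libraries would add about as many reads per kb to every gene, and the coefficient of variation over the 12 genes was 107% for the added CPM per kb against 64.8% for the ratio (143 and 51.5, 76.6 and 67, and 105 and 70.8 in Mix replicates 1, 2 and 3), a value carried by COX1, without which it was 32.5% against 61.6%. After the outcome over the 12 genes was seen, the question was calculated again, first as the Spearman correlation of level per kb with ratio (-0.937), then over the 6 called genes alone (24.6% against 40.2%), and last without each gene in turn (32.5 to 112% against 54.5 to 69.2%). The later values without COX1 and over the called genes go with carry-over but were picked with the outcome known, so carry-over and an unequal rise of transcripts may both remain open.

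By the number of called genes, Mix tumours lay close to MCFDCIS tumours. If 50% of the human RNA came from MCFDCIS-D4 cells with the profile of the pure W5 tumours, genes near 0 in those tumours would lie near 50% of their MCFDCIS level. Over 7 such genes, LGR5 and MUC16 among them, the median was 89.5% at W2 (quartiles 84.1 to 96.8) and 106% at W5 (102 to 117), which argues against it at both times. The largest rises in pure MCFDCIS-D4 W5 tumours bear on a smaller share. CYP4Z1, OLFM4, ENPP3 and PIGR stood there at 102, 632, 71.9 and 21.6 CPM. In Mix W5 tumours they stood at 1.30, 7.62, 2.48 and 0.707 CPM, against 1.30, 15.8, 2.89 and 0.692 in MCFDCIS W5 tumours. For these genes only, the values argue against more than a small share with the pure profile at W5. A changed profile of MCFDCIS-D4 cells in the mixture, or a smaller share at W2, may remain and was not tested. No pure MCFDCIS-D4 tumour at W2 was analysed here, so the W2 value rests on the W5 profile.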

How the results depend on the processing

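Leaving out libraries of groups not compared, and all leave-one-out values of the gene groups and of the shared D4 effect, were chosen after seeing the data. No called result reversed. The position of MCFDCIS-D4 tumours and r between the lines, which were not called, changed sign when some libraries were left out. Between the lines r was also positive with a mean of at least 5 CPM (0.0021) and with a pseudocount of 1 CPM (0.00285). Of 881 named gene results, other settings kept 8669 of their values and lost the call in 68, while leaving out a library kept 11553, lost 511 and gained 2. For 370 tests of gene groups these were 3118 kept, 177 lost and 24 gained, and 4999 kept, 86 lost and 69 gained. For called results, kept means the same direction and side of the threshold. For results not called, a change of direction could also count as kept. The estimated correlation left 5 of 164 list calls.

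With only the compared groups in the fit, counts were 5185 for D4 in MCFDCIS cells, 2974 for D4 in tumours, 26 for Mix against MCFDCIS at W5 and 116 for the time interaction. DESeq2 gave 73 for Mix against MCFDCIS at W5, 1 at W2 and 79 for the interaction. A mean of at least 5 CPM gave 6 for Mix at W5, with fewer genes tested, and r of 0.0427 for cells and xenografts. No intensity trend gave 1 for the interaction. With at least 2 log2 units in cells the position was 0.221 for MCFDCIS-D4 and 0.0586 for Mix tumours, and 0.0318 for Mix with a pseudocount of 1. Where no reason is given, the cause was not tested.

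Leaving out 1 library gave 936 to 5003 genes for D4 in MCFDCIS cells, 7606 to 10383 in MCF10A, 5918 to 9320 for MCFDCIS against MCF10A, 3396 to 5636 for D4 in tumours, 5 to 32 for Mix against MCFDCIS at W5, 4969 to 6934 for Mix against MCFDCIS-D4, 0 to 0 at W2, 387 to 1312 for time in MCFDCIS and 2273 to 4733 in Mix, 6079 to 9479 for the line interaction and 4 to 53 for the time interaction. The highest were without replicate 1 of MCF10A-D4 cells or of MCFDCIS-D4 tumours, except at W2. List calls ran from 156 to 172, r from -0.0267 to 0.0246 between lines and from 0.0247 to 0.0478 between cells and xenografts, and position from -0.00768 to 0.0906 for MCFDCIS-D4 and from 0.0289 to 0.0470 for Mix.

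Replicate numbers did not pair the samples: in no comparison were all 3 same-number correlations over 0.1. With a replicate block the count for Mix at W2 was 1 and that of the time interaction 10; the other counts stayed within 1.5 times (1485 for D4 in MCFDCIS cells, 7 for Mix at W5). The shallowest library, with 18839251 reads, limits mainly genes under 1 CPM.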

Other observations

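The descriptions below were made after the values were seen. In MCFDCIS-D4 cells, the list of amino acid response and unfolded protein genes was lower as a group: of 29 genes 7 fell, 1 rose and 21 did neither, with the same numbers when adjusted over the list alone (camera, adjusted p = 0.0036; adjusted p = 0.105 with an estimated correlation). Asparagine synthetase (ASNS) fell from 51.9 ± 3.25 to 27.8 ± 0.93 CPM and TRIB3 from 132 ± 12.5 to 73.6 ± 4.93 CPM. The surface glycoprotein CD24 rose from 84.6 ± 11.1 to 474 ± 5.86 CPM, and the Notch ligand JAG1 from 208 ± 7.26 to 410 ± 12.1 CPM.

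Endothelial genes moved in both directions from W2 to W5 in Mix tumours, where 4 of 16 markers rose and 1 fell, with the same numbers when adjusted over the list alone. PECAM1 fell from 22.6 ± 4.04 to 5.30 ± 0.68 CPM, while the receptor KDR rose from 38.5 ± 0.74 to 99.9 ± 13.2 CPM and ESM1 from 0.170 ± 0.086 to 2.89 ± 0.49 CPM. In MCFDCIS tumours PECAM1 fell from 18.5 ± 4.31 to 7.55 ± 3.00 CPM. Cultured MCFDCIS cells also held PECAM1 at 4.51 to 6.59 CPM and KDR at 1.47 to 1.84 CPM, in a table scaled separately. Mouse host reads cannot be separated either, so these changes cannot be read as endothelial content.

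Neighbouring genes on chromosome X were far lower in MCFDCIS than in MCF10A cells. FLNA stood at 10.6 CPM in MCFDCIS and 2844 in MCF10A cells. EMD, which encodes emerin (153607633 to 153609934), had 0 to 2 reads in the MCFDCIS libraries and none in the MCFDCIS-D4 libraries, against 1121 to 1793 reads in the MCF10A and MCF10A-D4 libraries. The next gene, RPL10, was at 356 ± 13.7 CPM in MCFDCIS and 376 ± 30.0 in MCF10A cells.

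Of 10 genes with at least 3 CPM in MCFDCIS cells and under 0.5 CPM in MCFDCIS-D4 cells, 6 were at 50% or more of the MCFDCIS level in MCFDCIS-D4 tumours at W5. ARSD was at 0.0671 CPM in MCFDCIS-D4 cells, and at 46.0 ± 2.05 CPM in MCFDCIS-D4 tumours against 54.7 ± 3.20 in MCFDCIS tumours. CDH13 was at 17 ± 16.8 against 15.5 ± 7.43 CPM in those tumours. ZNF331 was at 1.26 ± 1.13 against 9.48 ± 0.96 CPM. The cell and xenograft tables were scaled separately, and the library names do not show that MCFDCIS-D4 cells and tumours are the same line.

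In MCF10A-D4 replicate 1, 35 genes were more than 5-fold above both other replicates, every MCF10A library and 1 CPM. Among them were FOS, at 462 CPM against 83.0 and 86.7 in replicates 2 and 3, and POSTN, at 634 CPM against 75.2 and 66.5. MCFDCIS-D4 tumour replicate 1 correlated with the other replicates at r of 0.977 and 0.974 across genes, against 0.988 between those.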
